A study of Mus musculus with 128 samples.

How the data were processed

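The series holds 128 mouse liver samples: 106 single-cell RNA libraries made with Smart-seq3xpress and 22 ATAC-seq libraries. The RNA libraries cover wild-type B6C3F1 embryos from E11.5 to E19.5 (18 libraries), Foxa3Cre and AlfpCre lines in vivo (44), E15.5 liver cultured for 2 days (26), and P60 TbgCre livers on days 0, 2 and 7 after hepatectomy (18). The labels of all adult Pard3HMKO libraries give an injection of AAV-Tbg-Cre, and those of their controls give none. Names of groups follow the labels: Pard3HMKO and YapHMKO for the lines with the gene deleted, Pard3WT and YapWT for their controls.

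The RNA table holds counts for 40824 genes in 4264 cells, already selected by the authors. They were taken as reads; the sources used here do not say whether copies of 1 molecule were merged, so CPM and limits in reads rest on that reading. Per the submitters' processing notes, reads were handled with FastQC 0.11.9, Trimmomatic 0.39 and HISAT2 2.1.0 on builds GRCm38 and mm10; the counting tool and the gene annotation are not given in the sources used here. The deposited ATAC files list the peaks of 1 library each, with a score of 50 or more per peak. Per those notes they come from Trimmomatic 0.38, Bowtie2 2.2.5, SAMtools 1.3.1, HOMER and MACS 1.4.2 on mm10. ATAC coverage was not used here, only the presence of a peak, with 1-based coordinates.

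Cells are not independent, so their counts were summed within each library, the unit of every test but Fisher's exact test. A library held 7 to 133 cells and 4506130 to 86188713 reads; the median cell held 622917 reads and 7548.5 detected genes. All 4264 columns belonged to a sample. The 92 spike-in entries held 126 reads and were left out. No label states that libraries come from separate animals, so p-values over libraries measure only the spread between samples, which may be technical.

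Before the data were examined, the comparisons, tests, gene lists, rule for named genes and most alternatives were fixed. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr with the groups, TMM normalization, trended dispersion, and quasi-likelihood F tests with robust fits, 2-sided, with Benjamini-Hochberg adjustment within each comparison. A gene is called at an adjusted p below 0.05. The trended dispersion replaced the slower per-gene estimate after the design was fixed; the quasi-likelihood step still fits each gene's own spread. There were 4 fits, each with all its groups: the wild-type trend (15662 genes, slope per day), the in vivo lines (18572), the cultures (16715) and the adult livers (15391). The standard error is the absolute log2 fold change divided by the square root of F. Levels are CPM, reads scaled by the library's total times its TMM factor. A group with no read was given a floor of 3 counts where a fold is stated as a lower bound.

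Groups of genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01 and, as an alternative, an estimated correlation. There were 30 lists, written from general knowledge: 25 of functions and zones and 5 of markers of other cell types. A further pair of lists, the 200 genes rising and the 200 falling fastest with age in wild type, was added to every comparison. That pair is circular for the trend itself and is no independent evidence there; for the other comparisons it comes from other libraries. Of 435 list tests called with the preset correlation, 207 were called with the estimated one. Members of each list were also adjusted over the list alone.

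Named genes follow a rule: Pard3, Yap1, Alb and Afp always; the largest rises and falls among called genes (6 per direction in 9 main comparisons, 3 in the rest) with at least 10 CPM in a group and no overlap between the libraries compared, leaving out predicted, mitochondrial and ribosomal names; up to 4 members per list with the smallest adjusted p; and up to 4 ATAC regions per comparison, at members of the lists. Genes named outside it were chosen after their values were seen.

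For ATAC, the peaks of all libraries compared were merged into regions. A region was gained when every library of the first group and none of the second had a peak overlapping it, and lost in the reverse case. Gene spans came from the supplied GRCm38 annotation (21887 protein-coding genes), and near means within 10 kb. The annotation gives no strand or start site, so regions are placed against the gene span. Association with expression used Fisher's exact test, which takes genes as independent, and peak numbers an exact permutation test. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

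A cell was marked as holding markers of another cell type when it had reads for at least 50% of such a list; 1194 of 4264 cells (28.0%) were, of which 668 by the erythroid list, 406 by the macrophage and myeloid list, 61 by the stellate list and 59 by the endothelial list. They stayed in the sums. Xist and 4 Y genes, at 5 CPM or more in a cell, gave the sex of cells.

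Alternatives were RLE normalization, no filter on low counts, a fit with only the libraries compared, the replicate number as a block, sums without the marked cells, DESeq2 1.42.0, every library left out in turn, and for ATAC an equal number of peaks per library, peaks covering 50% of a region, and libraries left out. Others, added later, are named in the closing section. A result moved when a count changed by more than 1.5 times.

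Data were simulated with the depth and trended dispersion of these libraries, without each gene's own spread. For 2 against 2 libraries at E17.5 edgeR found 34% of 2-fold and 66% of 4-fold changes, with 3.8% of calls false. DESeq2, not simulated for the in vivo lines, had a false share of 12 to 23.1%. None of the 30 lists of unchanged genes was called, but correlated lists were not tested. The ATAC rule recovered all 200 gained and 200 lost regions but called 28 unchanged ones with 6 libraries and 305 with 4. Genes changed under 4-fold are thus often missed, and a gene not called is not shown to be unchanged.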

Results

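Reads of 4264 single liver cells were collected in 106 RNA libraries, and open chromatin in 22 ATAC libraries. They cover wild-type embryos from E11.5 to E19.5, livers in which Foxa3Cre or AlfpCre was used to delete Pard3 or Yap, cultured E15.5 livers given PD, TPPB or U0126, and adult livers after hepatectomy. Each RNA library sums 7 to 133 cells. Groups hold 2 libraries unless another n is given. Changes are log2 fold changes ± SE and levels are mean CPM ± SD over the libraries of a group. Adjusted p-values come from edgeR for genes and from camera for lists of genes.

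Pard3 reads were not called lower in any group labelled Pard3HMKO of the embryonic and postnatal lines. At E17.5 the Foxa3Cre Pard3HMKO libraries held 31.3 ± 7.49 CPM of Pard3 and their controls 22.0 ± 7.74 (0.50 ± 0.21, adjusted p = 0.127). At E11.5 the levels were 19.6 ± 0.420 and 24.6 ± 1.06 (−0.33 ± 0.21). These are counts over the whole gene, and which exons are deleted is not given, so the loss of Pard3 was not tested. Yap1 was counted over the whole gene too. At E15.5 it fell from 64.7 ± 13.2 CPM in YapWT to 1.93 ± 2.50 in YapHMKO (−5.02 ± 0.55, adjusted p = 8.22e-06), and in culture from 179 to 4.43 CPM (−5.33 ± 0.43, adjusted p = 1.84e-07). At E17.5 it did not fall: the libraries labelled YapHMKO held 44.6 CPM and the YapWT libraries 28.1 (0.67 ± 0.45, adjusted p = 0.404). That goes against the label, as do the libraries labelled Pard3HMKO YapHMKO with 37.9 ± 0.930 CPM against 26.2 ± 2.60 (0.53 ± 0.46, adjusted p = 0.54). Directions drawn from these E17.5 groups are given below for the labels, not for a loss of Yap1.

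**Figure D1:**
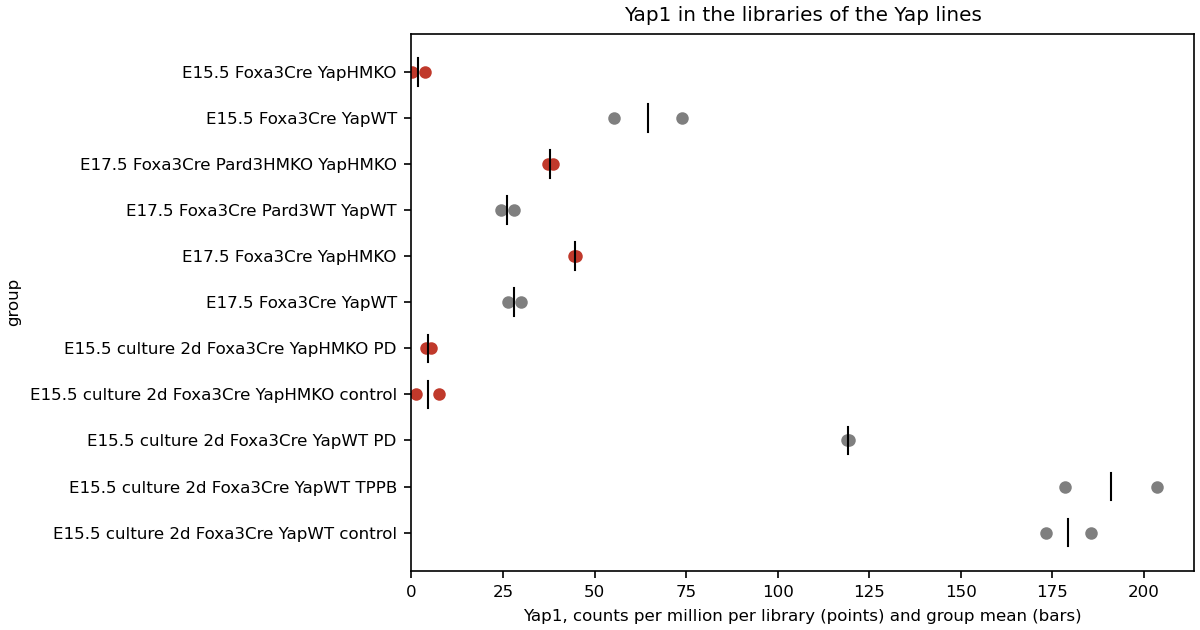
Yap1 reads per library in every group with a Yap label or its control. Points are libraries and bars are group means.

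In wild-type livers, genes of the working hepatocyte rose from E11.5 to E19.5 in a linear fit over age. Fbp1, an enzyme of glucose production, rose by 2.37 ± 0.19 per day, from 0.121 ± 0.108 to 4499 ± 34.0 CPM. G6pc rose by 2.27 ± 0.18 per day and Eif4ebp3 by 2.19 ± 0.16. Cyp4a14, Iigp1 and Serpina3k had no read at E11.5 and reached 103 ± 32.0, 149 ± 5.72 and 31.4 ± 13.7 CPM at E19.5. Mdk, a growth factor of embryonic tissue, fell by 1.32 ± 0.09 per day, from 355 ± 9.56 to 0.550 ± 0.156 CPM. The RNA-binding protein gene Lin28a fell by 1.73 ± 0.15 per day, and Sox11, Onecut3 and Car4 went from 46.1, 15.1 and 27.1 CPM to none. The embryonic globin gene Hbb-y went from 221 ± 307 CPM to none. Alb rose more slowly, by 0.22 ± 0.04 per day (adjusted p = 4.42e-05), from 19430 ± 68.4 to 63770 ± 332 CPM, but not evenly (52430 at E14.5 and 28550 at E15.5), while Afp had no called slope (−0.03 ± 0.03, adjusted p = 0.438), with 39420 ± 226 CPM at E11.5, 62200 at E14.5, 41200 at E15.5 and 39060 ± 2584 at E19.5. The E15.5 and E16.5 libraries stand apart, with 4506130 to 7965011 reads (15470716 or more at other ages) and −81.7 to −55.6 on the second principal component (3.35 to 90.8 at other ages). Pard3 rose by 0.17 ± 0.04 per day (27.4 to 46.7 CPM). The slope of Yap1 was 0.11 ± 0.04, with 55.7 CPM at E11.5, 39.5 at E13.5, 103 at E17.5 and 61.1 at E19.5.

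Whole groups of genes moved with age. All 21 complement and coagulation genes rose (camera adjusted p = 3.19e-22, and adjusted p = 0.00016 with an estimated correlation), as did all 22 cytochrome P450 genes (1.86e-18 and 8.24e-06), with the same counts when adjusted over the list alone. Of 19 bile acid genes 16 rose (17 over the list alone), among them the bile salt pump Abcb11 (0.74 ± 0.04) and the uptake carrier Slc10a1 (1.58 ± 0.10). Gluconeogenesis (10 of 12, 12 over the list alone), hepatocyte maturation (17 of 20, with Cyp2e1 at 1.79 ± 0.11), urea cycle (16 of 19 with 1 lower), periportal (14 of 16 with 1 lower), fatty acid oxidation (14 of 16 with 1 lower) and acute phase genes (9 of 14 with 1 lower) rose too, and all of these were called with the estimated correlation. Genes of cell division fell: 20 of 22 G2 and M phase genes (21 over the list alone; Ube2c −0.57 ± 0.07, Cdk1 −0.40 ± 0.06; adjusted p = 1.49e-14) and 18 of 22 S phase genes (Mcm7 −0.39 ± 0.04; adjusted p = 1.16e-10). The calls for both were lost with an estimated correlation (adjusted p = 0.116 and adjusted p = 0.0901). So were those of fatty acid synthesis (7 of 13 rose, adjusted p = 0.237 with an estimated correlation), the interferon response (8 of 17 rose and 2 fell, adjusted p = 0.237) and apical junction genes (14 of 35 rose and 2 fell, adjusted p = 0.116; Cldn1 0.40 ± 0.04). Hepatoblast genes were split, with 5 of 15 rising and 6 falling. In all, edgeR called 2897 genes rising and 2673 falling with age among 15662 (n = 18 libraries).

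In Foxa3Cre Pard3HMKO livers at E11.5, Dqx1, a gene of a helicase-like protein, fell from 86.3 ± 46.5 to 8.01 ± 3.17 CPM (−3.43 ± 0.43, adjusted p = 0.000233), and Hadhb, an enzyme of fatty acid oxidation, from 98.2 ± 53.5 to 42.1 ± 5.49 (−1.22 ± 0.22). Alb (0.20 ± 0.12) and Afp (−0.04 ± 0.13) were not called. In total 9 genes were higher and 5 lower (513 at an unadjusted p below 0.05), no list was called, and 0 genes were called with only the libraries compared in the fit.

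At E13.5 edgeR called 0 genes, while 665 had an unadjusted p below 0.05 and DESeq2 called 3. Alb held 24200 ± 587 CPM in Pard3HMKO and 23090 ± 982 in controls (0.07 ± 0.12), and Afp 26400 ± 269 and 25940 ± 264. Without Pard3WT replicate 1 the count was 1. Cells with markers of other types were 90.2% and 66.7% of controls and 65.8% and 71.1% of Pard3HMKO. Of the lists, endothelial markers shifted most upward (median 3.98, adjusted p = 0.00421, and 0.965 with an estimated correlation). Their sums overlapped: 31.6 and 25.1 CPM in Pard3HMKO, 24.1 and 27.8 in controls. P450 genes shifted downward (median −0.39, adjusted p = 0.0319 and 0.965). No member of either was called, adjusted over list or all genes.

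By E15.5 a small set of genes differed. The class I antigen genes H2-Q7 (11.8 ± 8.91 against 0.209 ± 0.0354 CPM, 5.76 ± 0.52) and H2-Q6 (5.32 ± 0.82) were higher in Pard3HMKO. Aen, a nuclease gene of the p53 response, was lower (−1.91 ± 0.38), with Samd8 (−1.46 ± 0.29) and Txnip (−1.43 ± 0.29). Alb was not called (69120 ± 3568 and 63390 ± 5554 CPM). Glycolysis and hypoxia genes shifted downward (adjusted p = 3.43e-08, and adjusted p = 0.0233 with an estimated correlation), with 1 of 20 called lower, Egln3 (−5.30 ± 0.98), and 7 adjusted over the list alone. Of 20 hepatocyte maturation genes 2 were higher, Otc (0.55 ± 0.12) and G6pc (9.08 ± 1.83), the same number adjusted over the list alone (adjusted p = 0.784 with an estimated correlation). Erythroid markers shifted downward with 0 of 15 called, 7 adjusted over the list alone (Alas2 −3.04 ± 0.78; adjusted p = 1.65e-10, and adjusted p = 0.235 with an estimated correlation). Cells with markers of other types were 24.4% and 14.3% of the controls and 2.38% and 4.55% of Pard3HMKO. In all 26 genes were higher and 18 lower (1441 unadjusted), with 19 called without Pard3WT replicate 1 and 0 with only the libraries compared in the fit. A fit that leaves 1 library in a group assumes that this library varies as the other groups do.

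At E17.5 the Pard3HMKO livers differed broadly. Alb fell from 182200 ± 7878 to 74520 ± 18000 CPM (−1.29 ± 0.12, adjusted p = 6.27e-08) and Afp from 133700 ± 19250 to 61590 ± 9546 (−1.12 ± 0.13, adjusted p = 1.05e-06). Mdk, which falls with age in wild type, was higher (16.7 ± 9.46 against 0.499 ± 0.382 CPM, 5.19 ± 0.86), with Arhgap36 (5.14 ± 1.05), Steap1 (4.59 ± 0.77) and Pcna-ps2 (4.43 ± 0.70). The X-inactivation transcript Xist had the largest rise (16.3 ± 2.85 against 0.0857 ± 0.121 CPM, 7.27 ± 0.79). The largest falls were Zc3h12d (−3.68 ± 0.96), Egr2 (−3.63 ± 0.65), Hsd17b6 (−3.37 ± 1.12), the iron hormone gene Hamp (192 ± 72.4 to 20.7 ± 15.2 CPM, −3.23 ± 0.98), the hypoxia gene Ankrd37 (−3.04 ± 0.50) and the secreted growth factor gene Fgl1 (1049 ± 247 to 133 ± 26.4 CPM, −2.98 ± 0.42).

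Groups of hepatocyte genes fell together at E17.5. Of 21 complement and coagulation genes 17 fell (18 adjusted over the list alone; F10 −1.13 ± 0.10, F2 −1.03 ± 0.09, Serpinc1 −1.11 ± 0.10; adjusted p = 1.14e-21, and adjusted p = 0.00459 with an estimated correlation). Of 20 hepatocyte maturation genes 12 fell and 2 rose (15 and 2 over the list alone; Fah −1.44 ± 0.14, Ttr −1.14 ± 0.10; adjusted p = 0.00658 with an estimated correlation). Also lower were 13 of 20 glycolysis genes with 1 higher (Ldha −1.32 ± 0.09), 13 of 22 P450 genes, 11 of 16 fatty acid oxidation genes with 1 higher, 7 of 12 gluconeogenesis genes (10 over the list alone), 8 of 19 urea cycle genes with 1 higher, 7 of 16 periportal, 8 of 17 acute phase and 8 of 19 bile acid genes (11 over the list alone). Each of these calls was kept with an estimated correlation. Of the genes that rise most with age in wild type 45 of 199 fell, such as Pemt (−1.60 ± 0.16), which makes phosphatidylcholine, and Txnip (−2.67 ± 0.29). Of those that fall with age 28 of 189 rose, such as Marcksl1 (3.58 ± 0.41). Genes of DNA replication rose, with 14 of 22 S phase genes (17 over the list alone; Mcm3 3.16 ± 0.47, Cdt1 1.37 ± 0.31; adjusted p = 2.06e-09, and adjusted p = 0.127 with an estimated correlation) and 3 of 22 G2 and M phase genes (2 over the list alone; Ccnb2 1.48 ± 0.41; adjusted p = 0.444 with an estimated correlation).

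Several other lists were not called at this stage. Of 35 apical junction and polarity genes 2 were higher and 4 lower (adjusted p = 0.997), of 23 YAP target genes 4 and 1 (adjusted p = 0.742), of 19 ERK target genes 2 and 3 (adjusted p = 0.997) and of 15 hepatoblast genes 6 and 4 (adjusted p = 0.214). edgeR called 1316 genes higher and 1460 lower at E17.5. The count was 1082 without cells holding markers of other types and as low as 1605 with 1 library left out. The 10 most abundant genes took 39.4% and 40.4% of the control reads and 30.0% and 25.5% of the Pard3HMKO reads. Cells with markers of other types were 5.45% and 3.33% of the controls and 23.5% and 12.9% of Pard3HMKO. Of 65 Pard3HMKO cells 44 held only Y transcripts and 19 both Xist and Y transcripts, while 114 of 115 control cells held only Y transcripts.

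**Figure D2:**
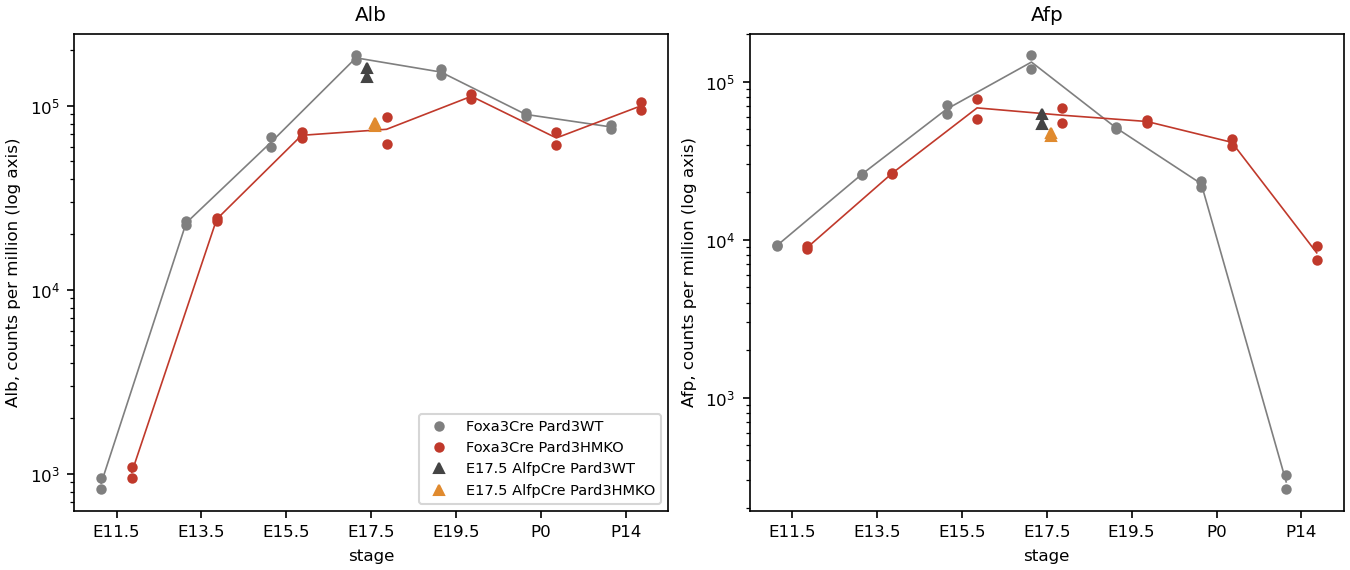
Alb and Afp reads per library by stage on a log axis. Grey circles are Foxa3Cre Pard3WT, red circles Foxa3Cre Pard3HMKO with lines through the group means, and triangles the AlfpCre libraries at E17.5.

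With AlfpCre in place of Foxa3Cre, Alb again fell in Pard3HMKO at E17.5, from 151300 ± 11920 to 79140 ± 2201 CPM (−0.94 ± 0.12, adjusted p = 1.54e-05), while Afp was not called (−0.34 ± 0.13, adjusted p = 0.149). Iigp1, an interferon-induced GTPase gene, fell from 103 ± 32.6 to 1.35 ± 0.712 CPM (−6.23 ± 0.59), with Eif4ebp3 (−6.06 ± 0.84), Serpina4-ps1 (−5.48 ± 1.24) and Cyp2c69 (−5.30 ± 0.71). The interferon genes Ifit3 (−10.68 ± 2.62) and Rsad2 (−8.80 ± 2.09) also fell, but their control levels varied (87.0 ± 123 and 85.3 ± 120 CPM). The ammonium transporter gene Rhbg (3.48 ± 0.41), the actin-bundling gene Fscn1 (2.94 ± 0.40), Tma7-ps (3.96 ± 0.53), Lzts1 (2.77 ± 0.56) and Icosl (2.71 ± 0.45) were higher. Hamp was higher (214 ± 46.3 against 21.3 ± 8.73 CPM, 3.33 ± 0.97), the reverse of the Foxa3Cre line.

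Many of the same lists fell with AlfpCre: 16 of 21 complement genes (17 over the list alone; Fgb −1.63 ± 0.16; adjusted p = 7.83e-27, and adjusted p = 0.00232 with an estimated correlation), 11 of 20 hepatocyte maturation genes with 1 higher (14 and 2; adjusted p = 0.00232), 8 of 22 P450 genes (16), 6 of 12 gluconeogenesis genes, 7 of 16 fatty acid oxidation genes with 2 higher, and 67 of 199 genes that rise with age with 1 higher (90 and 1 over the list alone; adjusted p = 1.21e-06). Acute phase, periportal, stress response, glycolysis and bile acid genes were lower with either correlation. Of 15 pericentral genes 5 were higher (Lect2 1.83 ± 0.18, Lgr5 4.42 ± 0.86, camera adjusted p = 0.00997 with an estimated correlation). Called with the preset correlation alone were S phase (4 of 22 higher, 10 over the list alone; adjusted p = 0.153 with an estimated correlation), G2 and M phase (1 of 22 higher, adjusted p = 0.127) and interferon genes (3 of 19 lower, adjusted p = 0.15). In all 414 genes were higher and 566 lower (2913 unadjusted). The count was 145 without cells holding markers of other types (29.9% and 47.1% of Pard3HMKO, 41.5% and 30.4% of controls), 578 with only the libraries compared and as low as 485 with 1 library left out. The Foxa3Cre and AlfpCre comparisons share no library. 209 genes were higher in both (29.3 by chance), 414 lower in both (44.5 by chance) and 28 opposite (72.7 by chance).

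At E19.5 Serpina6, the gene of the corticosteroid carrier protein, was higher in Pard3HMKO (3017 ± 298 against 262 ± 14.6 CPM, 3.53 ± 0.23, adjusted p = 3.51e-10), with Fscn1 (3.23 ± 0.42) and BC028528 (3.07 ± 0.78). The P450 gene Cyp2c69 fell from 284 ± 29.3 to 1.45 ± 0.0587 CPM (−7.61 ± 0.78) and the steroid enzyme gene Hsd3b6 from 54.4 ± 9.83 to 0.157 ± 0.0124 (−8.41 ± 1.72). Acta2 was lower with controls that varied (21.9 ± 30.6 CPM, −7.76 ± 2.11). Alb fell by 0.44 ± 0.12 (152500 ± 7831 to 112600 ± 4854 CPM, adjusted p = 0.0271) and Afp was not called (0.14 ± 0.13). Dlk1, a surface protein of hepatoblasts, was higher (1.64 ± 0.09), as were the fetal genes Igf2bp1 (1.49 ± 0.21) and Igf2 (0.35 ± 0.07). 5 of 15 hepatoblast genes rose (10 over the list alone with 1 lower; adjusted p = 1.69e-06, and adjusted p = 0.00105 with an estimated correlation).

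Gluconeogenesis was lower at E19.5 in 7 of 12 genes (8 over the list alone; G6pc −6.21 ± 0.61, Fbp1 −3.20 ± 0.37; adjusted p = 2.39e-11, and adjusted p = 0.00105 with an estimated correlation), fatty acid oxidation in 11 of 16 with 1 higher (Cpt1a −1.80 ± 0.27), P450 genes in 11 of 22 (15; the bile acid enzyme Cyp7a1 −3.75 ± 0.51), hepatocyte maturation in 10 of 20 (11; Apoc3 −2.17 ± 0.20), complement in 11 of 21 with 1 higher (fibrinogen Fgg −1.76 ± 0.16), bile acid genes in 8 of 19, immediate early genes in 10 of 18 (14; Jun −1.83 ± 0.20), and stress response, acute phase and fatty acid synthesis genes in 6 of 18, 4 of 17 and 4 of 14. Of the genes that rise with age 69 of 199 were lower (81 over the list alone with 2 higher; adjusted p = 1.37e-05). These calls were kept with an estimated correlation. Lost with it were S phase (9 of 22 higher, 16 over the list alone, Tk1 1.11 ± 0.19; adjusted p = 0.0709 with an estimated correlation) and G2 and M phase genes (4 of 22 higher, 12; adjusted p = 0.166), among others. Endothelial (0 of 15 called, adjusted p = 0.408) and macrophage markers (1 of 17 lower, Mpo −5.30 ± 1.27, adjusted p = 0.321) shifted downward beside them, and cells with markers of other types were 39.3% and 32.4% of the controls and 27.9% and 26.2% of Pard3HMKO. Of 133 Pard3HMKO cells 122 held only Xist and 0 only Y transcripts, against 62 and 40 of 132 control cells. edgeR called 559 genes higher and 732 lower (381 in all without cells holding markers of other types, 586 to 794 with 1 library left out), and with RLE normalization 413 higher and 920 lower, a shift of −12.3 points.

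At birth more genes were called than at any other stage of Pard3HMKO in vivo. In Pard3HMKO Serpina6 stood at 3413 ± 97.2 CPM against 25.7 ± 8.80 (7.05 ± 0.27, adjusted p = 2.04e-15), and Afp at 41450 ± 3290 against 22630 ± 1257 (0.87 ± 0.13, adjusted p = 1.35e-05). Alb fell by 0.42 ± 0.12 (89780 ± 2820 to 66890 ± 7858 CPM). Kcnip1 was present at 12.0 ± 2.83 CPM with no read in the controls, and the pre-B cell gene Vpreb1 was higher (8.51 ± 2.62). The lipid droplet gene Cidec (35.1 ± 1.02 CPM in controls) and Ankrd55 (38.2 ± 15.4) had no read in Pard3HMKO, and Eif4ebp3 fell from 387 ± 34.4 to 0.0948 ± 0.0179 CPM (−11.96 ± 0.97). All 16 fatty acid oxidation genes fell (Cpt1a −5.25 ± 0.31; adjusted p = 1.44e-22, and adjusted p = 1.23e-05 with an estimated correlation). Cholesterol synthesis rose in 14 of 16 genes (16 over the list alone; Fdps 3.34 ± 0.15; adjusted p = 0.000458 with an estimated correlation).

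At P0 19 of 22 P450 genes were lower with 2 higher, 16 of 20 hepatocyte maturation genes lower (17 over the list alone; Apoc3 −3.86 ± 0.22), 17 of 21 complement genes lower with 2 higher, 16 of 19 bile acid genes lower (18; Abcb11 −2.18 ± 0.19), 13 of 19 urea cycle genes lower (14), 12 of 16 periportal and 8 of 12 gluconeogenesis genes lower with 1 higher in each, and 10 of 17 acute phase genes lower (haptoglobin Hp −6.76 ± 0.49). Of the genes that rise with age 108 of 199 were lower and 4 higher. Hepatoblast genes were higher in 8 of 15 and lower in 2 (9 and 3 over the list alone; Dlk1 4.91 ± 0.11). Fatty acid synthesis was tested as higher (7 of 14 higher, 2 lower; Fasn 3.01 ± 0.17, Plin2 −3.03 ± 0.15; adjusted p = 0.0372 with an estimated correlation), while its median was 0.84 and its mean −0.10. All these calls were kept with an estimated correlation. All 22 G2 and M phase genes were higher (Ccnb2 3.76 ± 0.45; adjusted p = 1.02e-13, and adjusted p = 0.108 with an estimated correlation), with 20 of 22 S phase genes (21; Mcm6 1.68 ± 0.20; adjusted p = 0.0594). The totals were 1957 higher and 2093 lower. Of the cells, 76.7% and 92.0% of Pard3HMKO and 63.8% and 50.0% of the controls held markers of other types. 17 of 55 Pard3HMKO cells and 0 of 118 control cells held only Xist.

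At P14 Afp, silent in the mature liver, remained at 8260 ± 1187 CPM in Pard3HMKO against 292 ± 41.4 (4.82 ± 0.15, adjusted p = 7.66e-17), and Alb was higher (100100 ± 7623 against 76800 ± 2894 CPM, 0.38 ± 0.12). The imprinted growth genes Igf2 (3.72 ± 0.08), H19 (2.54 ± 0.09) and Peg3 (2.71 ± 0.14) were higher, within 9 of 15 hepatoblast genes (adjusted p = 5.01e-11, and adjusted p = 1.84e-05 with an estimated correlation). All 16 cholesterol synthesis genes rose (Fdps 4.46 ± 0.17, Sqle 4.26 ± 0.17; adjusted p = 1.78e-43, and adjusted p = 1.58e-05 with an estimated correlation). Actin and adhesion genes were higher in 16 of 29 and lower in 2 (20 and 2 over the list alone; Anxa2 3.75 ± 0.18; adjusted p = 0.00327 with an estimated correlation), and biliary genes in 7 of 17 (Krt8 2.12 ± 0.17; adjusted p = 0.0175). Yap1 was higher (44.8 ± 0.895 against 17.6 ± 5.63 CPM, 1.35 ± 0.47, adjusted p = 0.0482). Cxcl10 (9.61 ± 1.73; 349 ± 412 CPM) and Sprr1a (9.41 ± 1.60) rose with wide spread, and Plat was at 12.0 ± 15.0 CPM with no read in controls. Adm2 fell (−8.79 ± 0.86), and Extl1 went from 12.2 ± 1.44 CPM to none.

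Other lists at P14 were called with the preset correlation alone. Higher were G2 and M phase (15 of 22, 21 over the list alone; adjusted p = 0.165 with an estimated correlation), S phase (10 of 22, 13; adjusted p = 0.28), complement (15 of 21, 17; adjusted p = 0.0594) and apical junction genes (8 of 35, 9; Cdh1 1.85 ± 0.20; adjusted p = 0.0594). Lower were urea cycle (8 of 19 with 1 higher; Arg1 −2.69 ± 0.21; adjusted p = 0.0594) and hepatocyte maturation genes (10 of 20 with 2 higher, adjusted p = 0.127). Fatty acid synthesis was tested as higher (5 of 14 higher, 3 lower; adjusted p = 0.165 with an estimated correlation) with a median of −0.11 and a mean of 0.29. The genes that rise with age were not called (14 of 199 higher, 26 lower, adjusted p = 0.306). edgeR called 1670 genes higher and 1424 lower. Without cells holding markers of other types, which takes out 31 of 35 and all 24 Pard3HMKO cells, the balance turned to 861 higher and 1477 lower. Markers of other cell types were held by 88.6% and 100% of the Pard3HMKO cells and 35.7% and 38.6% of the control cells, and 57 of 59 Pard3HMKO cells held only Xist while 97 of 113 control cells held only Y transcripts. Genes higher at P0 and P14 numbered 631 (176 by chance) and lower at both 508 (160.5), with 389 opposite (338.3). Between E17.5 and P14 268 were higher in both (118.3 by chance), 363 lower in both (111.9) and 458 opposite (232.2).

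**Figure D3:**
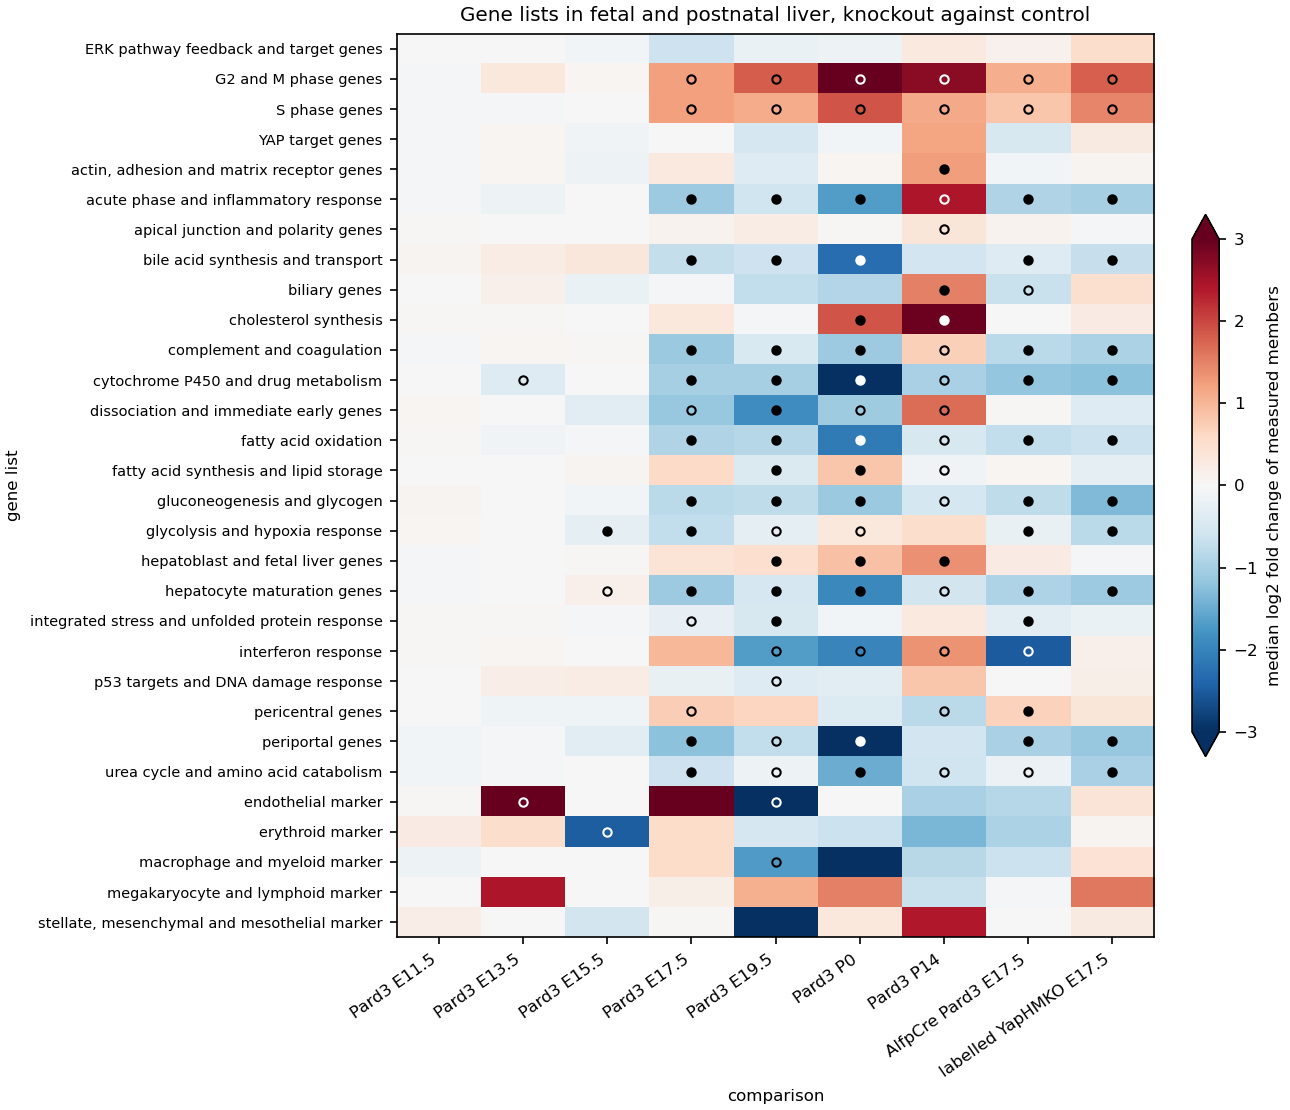
Median log2 fold change of each gene list in the in vivo comparisons, coloured from −3 to 3. A circle marks a list called by camera, filled where it is also called with an estimated correlation.

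In YapHMKO at E15.5 Yap1 fell, with reads left in 14 of 49 cells. Tma7-ps (44.7 ± 1.00 against 3.44 ± 0.897 CPM, 3.69 ± 0.50), the kinase gene Sgk1 (1.87 ± 0.39) and the reductase gene Akr1e1 (1.77 ± 0.28) were higher, and the pantetheinase gene Vnn1 (−2.94 ± 0.51) and the acute phase gene Serpina3n (−2.52 ± 0.44) lower. Alb (−0.19 ± 0.12) and Afp (−0.29 ± 0.13) were not called. edgeR called 27 genes higher and 29 lower (1814 unadjusted), 36 in all without YapWT replicate 2, 6 with only the libraries compared, 10 without cells holding markers of other types (1 of 21 and 10 of 28 in YapHMKO, 7 of 40 and 3 of 26 in YapWT) and 302 with DESeq2. S phase genes (0 of 22 called, 3 over the list alone; adjusted p = 4.07e-06, and adjusted p = 0.876 with an estimated correlation) and G2 and M phase genes (0 of 22; adjusted p = 0.00053 and adjusted p = 0.985) shifted upward, with medians of 0.49 and 0.88.

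At E17.5 the libraries labelled YapHMKO, in which Yap1 had not fallen, differed from YapWT in many genes. Alb fell from 178600 ± 950 to 85600 ± 9561 CPM (−1.06 ± 0.12, adjusted p = 1.13e-06) and Afp from 114000 ± 56.3 to 60810 ± 2589 (−0.91 ± 0.13). Higher were the pre-B cell gene Vpreb3 (5.00 ± 1.53), the replication checkpoint gene Clspn (4.87 ± 0.79), Pcna-ps2 (4.84 ± 0.71), Mdk (4.51 ± 0.73), Ifitm1 (4.37 ± 1.32) and Arhgap36 (3.75 ± 0.95). Lower were Serpina3k (−6.57 ± 1.38), Lims2 (−3.10 ± 0.67), Fgl1 (1115 ± 19.6 to 138 ± 47.7 CPM, −3.02 ± 0.42), the ephrin gene Efna1 (−2.82 ± 0.35) and Lrg1 (−2.73 ± 0.40). Complement genes were lower in 17 of 21 (adjusted p = 3.33e-20, and adjusted p = 0.00438 with an estimated correlation), hepatocyte maturation genes in 15 of 20 (16 over the list alone with 2 higher), glycolysis genes in 12 of 20, urea cycle genes in 10 of 19, P450 genes in 10 of 22, periportal genes in 9 of 16, fatty acid oxidation genes in 8 of 16 with 1 higher, gluconeogenesis genes in 8 of 12, bile acid genes in 9 of 19 with 1 higher and acute phase genes in 6 of 17. Of the genes that rise with age 53 of 199 were lower, and of those that fall with age 16 of 189 were higher. All these calls were kept with an estimated correlation. S phase genes were higher in 18 of 22 (19 over the list alone; Cdc6 4.71 ± 0.80; adjusted p = 4.4e-12, and adjusted p = 0.0825 with an estimated correlation) and G2 and M phase genes in 7 of 22 (11; adjusted p = 0.358). In all 1241 genes were higher and 1431 lower, 1071 without cells holding markers of other types. Cells with markers of other types were 53.3% and 75.8% against 55.1% and 34.5% in YapWT.

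The Pard3HMKO and the labelled YapHMKO livers at E17.5 shared many called genes: of 2776 and 2672, 709 were higher in both comparisons (87.9 by chance), 1078 lower in both (112.5 by chance) and 0 opposite (199 by chance). Over all genes the changes correlated at 0.263. Compared with each other directly, the libraries labelled YapHMKO and Pard3HMKO had 0 genes called by edgeR (814 unadjusted; DESeq2 was not run here), and the difference of both changes called 5 of 18572 genes. Between the labelled YapHMKO comparison at E17.5 and the one at E15.5, 5 genes were higher in both (1.8 by chance), 8 lower in both (2.2 by chance) and 13 opposite (4 by chance). The controls of the lines, Pard3WT and YapWT at E17.5, differed in 74 genes (36 higher in Pard3WT and 38 lower; 1780 unadjusted), among them Egr2 (2.92 ± 0.60), Ctnnbip1 (2.34 ± 0.33), Gdap10 (2.26 ± 0.47), Mcmdc2 (−2.01 ± 0.46), Akr1e1 (−1.64 ± 0.28) and Dhtkd1 (−1.51 ± 0.27). With 1 library left out 27 to 73 were called.

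The libraries labelled Pard3HMKO YapHMKO, in which Yap1 had not fallen either, gave a similar picture at E17.5. Alb fell from 162000 ± 2601 to 67050 ± 4809 CPM (−1.27 ± 0.12) and Afp by 1.01 ± 0.13. Xist (6.75 ± 0.81), Pcna-ps2 (5.73 ± 0.77), Mdk (4.62 ± 0.83), Arhgap36 (4.47 ± 1.00) and Tma7-ps (3.99 ± 0.55) were higher. Serpina3k (−7.42 ± 1.82), Bmp4 (−3.40 ± 1.16), Fgl1 (−3.35 ± 0.43), Ankrd37 (−3.19 ± 0.51) and Txnip (−2.89 ± 0.29) were lower. Of 21 complement genes 17 were lower (adjusted p = 1.32e-22, and adjusted p = 0.00301 with an estimated correlation), and 15 of 22 S phase genes higher (16 over the list alone; adjusted p = 0.101 with an estimated correlation). The cells of this line are not independent of the single lines. Of its 138 cells 127 (92%) matched 1 or 2 cells of the Pard3 or Yap lines in which genes held reads. The 1277 genes higher and 1433 lower thus largely repeat those comparisons. In Pard3HMKO YapHMKO replicate 1 the matched cells (95%) are all of Pard3HMKO, and in replicate 2 (12 of 20 cells) all of YapHMKO. The difference between the double and the Pard3 change, which called only Gm6472 (−3.14 ± 0.33, named after its value was seen), is void for the same reason.

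**Figure D4:**
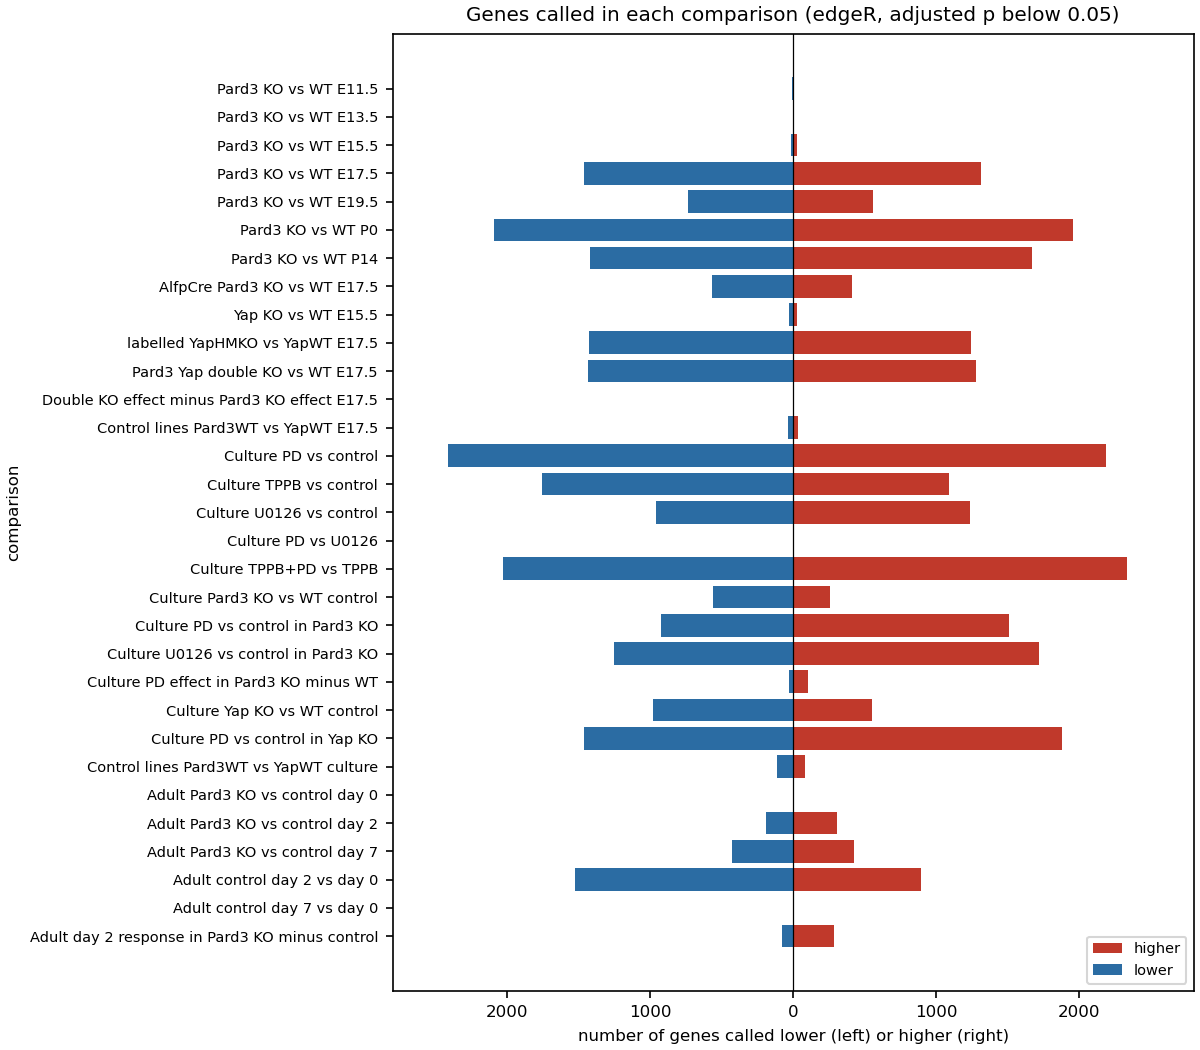
Genes called lower and higher in the comparisons of groups. Bars give counts at an adjusted p below 0.05.

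In cultured E15.5 livers the compound labelled PD turned on genes of lipid use and switched off those that answer to ERK signalling (n = 4 libraries per group, from the Pard3WT and YapWT lines). The fatty acid hydroxylase gene Cyp4a14 rose from 5.27 ± 0.816 to 1248 ± 398 CPM (7.87 ± 0.32). Cyp4a12b (9.71 ± 1.35), the fasting hormone gene Fgf21 (9.04 ± 0.80), Cyp2c55 (8.31 ± 1.18) and Dct (7.72 ± 0.92) rose as well. Ms4a4b went from 35.6 ± 10.1 CPM to none, and Akr1c18 (−9.19 ± 1.61), Igsf9 (−8.54 ± 1.14), Bean1 (−8.54 ± 1.03), the ERK feedback gene Spry2 (−8.48 ± 0.92) and Dnaic1 (−8.39 ± 0.75) fell. Alb fell by 0.56 ± 0.18 (adjusted p = 0.03) and Afp from 11760 ± 3980 to 4999 ± 1639 CPM (−1.25 ± 0.21). Pard3 rose (0.44 ± 0.14, adjusted p = 0.0243) and Yap1 was not called (−0.51 ± 0.25).

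All 16 fatty acid oxidation genes rose with PD (Acot1 5.53 ± 0.17, Ehhadh 6.44 ± 0.24; adjusted p = 7.8e-25, and adjusted p = 0.00162 with an estimated correlation), and 16 of 19 ERK target genes fell (17 over the list alone; Ier3 −5.32 ± 0.36, Dusp5 −5.14 ± 0.45, Etv4 −4.42 ± 0.39; adjusted p = 0.00357). Of 18 immediate early genes 12 fell and 1 rose. P450 genes rose in 12 of 22 with 1 lower, gluconeogenesis genes in 9 of 12, urea cycle genes in 13 of 19 with 1 lower and bile acid genes in 12 of 19 with 1 lower (Abcb11 3.91 ± 0.23). Of the genes that fall with age 37 of 136 fell and 4 rose. These calls were kept with an estimated correlation. Lost with it were hepatocyte maturation (14 of 20 higher with 2 lower, adjusted p = 0.0887 with an estimated correlation), cholesterol synthesis (12 of 16 higher with 1 lower, adjusted p = 0.0988), biliary (9 of 18 lower with 1 higher, adjusted p = 0.0674), YAP target (11 of 24 lower with 2 higher, adjusted p = 0.103) and S phase genes (6 of 22 lower, 8 over the list alone; adjusted p = 0.589). Macrophage markers fell in 9 of 13 (Lyz2 −3.90 ± 0.48; adjusted p = 0.0674) and erythroid markers rose in 4 of 10 (adjusted p = 0.41) beside them. The totals were 2188 genes higher and 2416 lower.

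TPPB, an activator of protein kinase C, lowered genes of the hepatocyte (n = 4 per group, with the same controls as PD). Alb fell from 14890 ± 6003 to 2195 ± 627 CPM (−2.77 ± 0.19, adjusted p = 6.71e-08) and Afp from 11760 ± 3980 to 3532 ± 306 (−1.72 ± 0.22). Dnaic1 (−8.42 ± 0.72), Smoc2 (−8.15 ± 1.24), Rnf138rt1 (−7.91 ± 1.67), Cyp2b9 (−7.53 ± 0.61), Akr1b7 (−6.81 ± 0.57) and the clotting factor gene F9 (−6.62 ± 0.77) had the largest falls. Serpinb9b reached 11.4 ± 3.67 CPM from none, and the chemokine gene Ccl7 (6.13 ± 7.78 to 1179 ± 896 CPM, 7.66 ± 1.13), Thbd (7.11 ± 1.21), Epha4 (6.97 ± 1.4) and Sema3c (6.62 ± 1.56) rose. Of 24 YAP target genes 11 rose and 1 fell (15 and 1 over the list alone; Tead1 1.49 ± 0.17, Amotl2 2.33 ± 0.29; adjusted p = 2.02e-06, and adjusted p = 0.0209 with an estimated correlation), and 10 of 19 ERK target genes rose (Etv4 2.51 ± 0.30; adjusted p = 0.0318).

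Of 21 complement genes 20 fell with TPPB (21 over the list alone; F10 −4.12 ± 0.17; adjusted p = 1.23e-32, and adjusted p = 0.00643 with an estimated correlation), 15 of 20 hepatocyte maturation genes (17 with 1 higher; Cps1 −3.77 ± 0.24), 15 of 16 cholesterol genes (16), 15 of 19 bile acid genes, 13 of 19 urea cycle genes with 1 higher, 14 of 22 P450 genes, 11 of 16 fatty acid oxidation genes with 1 higher, 7 of 12 gluconeogenesis genes with 1 higher, 9 of 16 periportal genes, and 57 of 159 genes that rise with age with 5 higher. All were kept with an estimated correlation. Lost with it were actin and adhesion (11 of 28 higher, adjusted p = 0.16 with an estimated correlation), S phase (3 of 22 higher, adjusted p = 0.381), hepatoblast (6 of 15 lower with 2 higher, adjusted p = 0.0929) and macrophage marker genes (8 of 13 lower with 1 higher, adjusted p = 0.0554). In all 1086 genes were higher and 1753 lower.

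U0126, an inhibitor of the MEK kinases, was given to the Pard3WT line. Cyp4a12b, Cyp2c55 and the defensin gene Defb1 reached 30.5 ± 10.1, 16.2 ± 2.41 and 15.8 ± 6.23 CPM from none. Bean1 went from 10.2 ± 2.94 CPM to none, Dio3 fell from a varied level (171 ± 234 CPM, −9.91 ± 2.66), and Dnaic1 fell (−9.51 ± 1.12). Alb fell from 12010 ± 782 to 5602 ± 21.6 CPM (−1.10 ± 0.25) and Afp by 1.59 ± 0.30. Fatty acid oxidation rose in 14 of 16 genes (15 over the list alone; adjusted p = 0.000975 with an estimated correlation) and ERK target genes fell in 13 of 19 (14; Dusp5 −6.77 ± 0.70; adjusted p = 0.00248). P450 genes rose in 10 of 22 and gluconeogenesis genes in 6 of 12, and immediate early genes fell in 9 of 18 with 1 higher, also with an estimated correlation. S phase genes fell in 12 of 22 (15; Mcm4 −2.81 ± 0.43; adjusted p = 2.32e-09, and adjusted p = 0.165 with an estimated correlation). Macrophage markers summed to 21.5 and 14.0 CPM against 70.2 and 66.8 in controls, of whose cells 35.3% and 20% held markers of other types (0% with U0126). edgeR called 1236 genes higher and 959 lower. PD and U0126 compared within the same line had 0 genes called by edgeR (611 unadjusted, DESeq2 3; 2 without PD replicate 1), with Alb at 0.54 ± 0.25 and Afp at 0.87 ± 0.30. That does not show that they act alike.

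Adding PD to TPPB raised many hepatocyte genes above TPPB alone. Alb stood at 6050 CPM against 1696 (1.83 ± 0.26, adjusted p = 8.13e-05). Afp was not called (0.19 ± 0.30). The sulfotransferase genes Sult2a1 and Sult1c2 and Rnf186 reached 26.7, 23.8 and 21.4 CPM from none, and Arg2, Slco3a1 and Irak3 went from 44.9, 41.8 and 41.0 CPM to none. Fatty acid oxidation (15 of 16, adjusted p = 0.00202 with an estimated correlation), hepatocyte maturation (16 of 20, 17 over the list alone; adjusted p = 0.007), cholesterol synthesis (13 of 16, adjusted p = 0.0182) and complement (17 of 21 with 1 lower, adjusted p = 0.0238) rose. ERK target genes fell in 18 of 19 (19; Etv4 −11.53 ± 0.84; adjusted p = 0.00202), YAP target genes in 17 of 24 with 1 higher (adjusted p = 0.0182), and S phase genes in 16 of 22 (21; adjusted p = 0.182). In all 2336 genes were higher and 2028 lower. Erythroid markers summed to 1894 and 685 CPM with both and 17.7 and 31.8 with TPPB, and macrophage markers to 14.0 and 19.8 against 61.7 and 49.9. Both TPPB comparisons share libraries, so their opposite signs are not independent. Nor are those below that share untreated Pard3HMKO or YapHMKO cultures or adult day 2 controls.

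In cultured Pard3HMKO livers Alb was lower than in Pard3WT (3954 against 12010 ± 782 CPM, −1.60 ± 0.26, adjusted p = 0.00163), as was Afp (−1.11 ± 0.30), and Pard3 itself was not called (−0.50 ± 0.20, adjusted p = 0.187). Duox2 and Serpinb9b were at 28.3 and 15.9 CPM with no read in the controls. Cyp2b9 (−6.17 ± 0.75), Igfbp6 (−4.67 ± 1.26) and Dnaic1 (−4.63 ± 0.81) fell. Complement genes fell in 16 of 21 (19 over the list alone; F10 −2.08 ± 0.22; adjusted p = 0.017 with an estimated correlation), hepatocyte maturation in 12 of 20 (16 with 1 higher; adjusted p = 0.017), cholesterol synthesis in 8 of 16 (10; adjusted p = 0.0183), fatty acid oxidation in 9 of 16 (adjusted p = 0.025), P450 genes in 8 of 22 (adjusted p = 0.0367), urea cycle in 8 of 19, bile acid in 7 of 19 and hepatoblast genes in 4 of 15 (adjusted p = 0.0371). Lost with an estimated correlation were ERK target (3 of 19 higher, adjusted p = 0.0713), YAP target (4 of 24 higher with 1 lower, adjusted p = 0.121) and apical junction genes (3 of 35 lower, adjusted p = 0.0713). In all 258 genes were higher and 561 lower (2701 unadjusted). With 1 library left out 330 to 574 were called.

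In the same Pard3HMKO cultures PD raised Alb (0.89 ± 0.25, adjusted p = 0.0278), Cyp3a59 (8.92 ± 1.4) and Fgf21 (7.37 ± 0.95), and Crct1 and Cxcl5 went from 69.0 and 12.0 CPM to none while the heat shock gene Hspa1a fell (−9.05 ± 1.67). Fatty acid oxidation rose in 15 of 16 genes (adjusted p = 0.00128 with an estimated correlation), hepatocyte maturation in 16 of 20 (19 over the list alone; adjusted p = 0.00737) and complement in 14 of 21 (adjusted p = 0.0401), and ERK target genes fell in 9 of 19 (12; adjusted p = 0.0104). The totals were 1506 higher and 921 lower. U0126 raised Alb as well (1.22 ± 0.25), with Rnf186 (8.85 ± 1.00) and Mogat1 (20.4 CPM from none), and Traf1 and Rspo3 went from 27.1 and 13.4 CPM to none while Crct1 fell (−8.91 ± 2.36). Fatty acid oxidation (15 of 16) and hepatocyte maturation genes (16 of 20, adjusted p = 0.00681 with an estimated correlation) rose and ERK target genes fell (13 of 19, 17 over the list alone; adjusted p = 0.00681), within 1719 genes higher and 1251 lower.

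The answer to PD differed between Pard3HMKO and Pard3WT in 135 genes (104 higher and 31 lower; 1884 unadjusted). Spry2 (9.91 ± 1.89), Dnaic1 (9.76 ± 1.23) and Spred2 (6.44 ± 0.98) were higher in that difference, the heat shock gene Hspa1b (−7.11 ± 1.37), Wfdc2 (−5.93 ± 1.19) and the death receptor gene Fas (−2.14 ± 0.47) lower, and Alb was not called (1.45 ± 0.35, adjusted p = 0.0816). Complement (3 of 21 higher, 14 over the list alone; adjusted p = 0.131 with an estimated correlation) and ERK target genes (5 of 19 higher, 11 with 1 lower; adjusted p = 0.131) were called with the preset correlation alone, and no list was called with the estimated one. Every library left out moved this count: without Pard3HMKO control replicate 1 or 2 it was 78 or 66, without Pard3HMKO PD 74 or 65, without Pard3WT control 58 or 73, and without Pard3WT PD 54 or 32.

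Cultured YapHMKO livers held Yap1 reads in 16 of 41 cells. Alb fell from 17770 to 3546 CPM (−2.33 ± 0.26) and Afp by 1.62 ± 0.30. The prostaglandin enzyme gene Ptges and Arl4d reached 33.3 and 14.8 CPM with no read in controls, Adm rose (7.08 ± 1.76), Nts went from 15.1 CPM to none, and Olfm4 (−9.34 ± 2.13) and Sult2a2 (−9.04 ± 1.08) fell. Complement (17 of 21, 19 over the list alone; adjusted p = 0.0258 with an estimated correlation), hepatocyte maturation (13 of 20, adjusted p = 0.0262) and cholesterol synthesis genes (9 of 16, adjusted p = 0.0308) fell, as did macrophage markers (6 of 13, 8; Lyz2 −7.55 ± 0.79; adjusted p = 0.0308). YAP target genes were not called as a list. Cells with markers of other types were 15.8% and 50.0% of the YapWT controls and 0% of YapHMKO. In all 550 genes were higher and 983 lower, and 292 were called with only the libraries compared. PD given to these YapHMKO cultures raised Alb to 12580 CPM (1.83 ± 0.26), Sult2a2 (9.98 ± 1.10), and Extl1 and Adamts15 (21.9 and 16.3 CPM from none), while Adm and Clic6 went from 46.9 and 10.6 CPM to none and Ptges fell (−8.22 ± 1.89). Fatty acid oxidation rose in 15 of 16 genes (adjusted p = 0.00221 with an estimated correlation) and complement in 16 of 21 (adjusted p = 0.0231), and ERK target genes fell in 10 of 19 (adjusted p = 0.0345), within 1880 higher and 1465 lower.

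The untreated cultures of the Pard3WT and YapWT control lines differed in 194 genes (80 higher in Pard3WT and 114 lower; 2078 unadjusted). Pgm5 and Tcea1-ps1 were at 14.7 and 10.9 CPM with no read in YapWT, AA465934 was higher (4.63 ± 0.40), and the urinary protein gene Mup7, Olfm4 and Mug1 had no read in Pard3WT and 47.1, 30.1 and 17.1 CPM in YapWT. P450 genes were lower in 4 of 22 (Cyp2e1 −7.14 ± 0.94; adjusted p = 0.0137 with an estimated correlation) and genes that rise with age in 15 of 159 (adjusted p = 0.0137). Macrophage markers summed to 70.2 and 66.8 CPM in Pard3WT and 576 and 1042 in YapWT, and 50% of the cells of YapWT replicate 2 held markers of other types. The count was 514 without such cells.

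**Figure D5:**
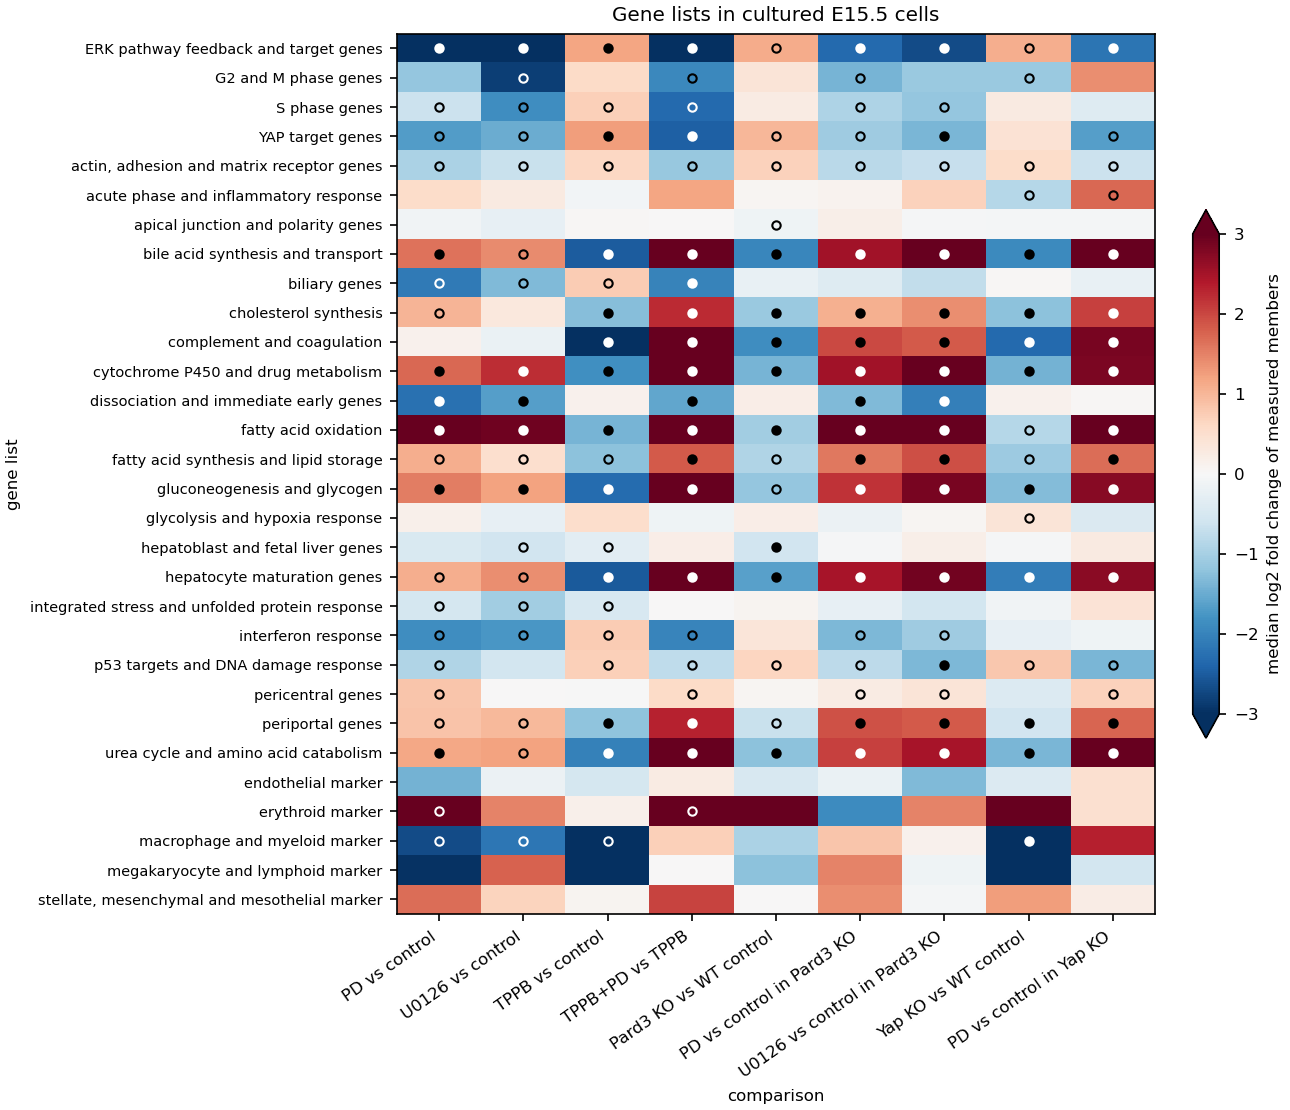
Median log2 fold change of each gene list in the culture comparisons, coloured from −3 to 3. Circles mark lists called by camera, filled where also called with an estimated correlation.

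In the adult TbgCre livers 2 days after hepatectomy, many genes of the mature hepatocyte were lower in the controls than at day 0. The carbonic anhydrase gene Car3 fell from 3274 ± 519 to 8.71 ± 4.84 CPM (−8.46 ± 0.75), the bile acid enzyme gene Cyp8b1 from 156 ± 79.1 to 0.218 ± 0.309 (−8.69 ± 0.83), and Serpinb1a (−9.06 ± 1.41), Sult2a7 (−9.05 ± 1.39), Hsd3b5 (−8.93 ± 0.93) and Car1 (−8.23 ± 1.32) fell. The metal-binding protein gene Mt2 rose from 7.15 ± 0.602 to 4734 ± 207 CPM (9.37 ± 1.83), with Cxcl14 (10.21 ± 0.82), Sult1e1 (9.30 ± 1.33), Serpina3i (9.27 ± 1.03), the basement membrane gene Nid1 (8.47 ± 0.82) and Akr1b7 (8.40 ± 1.52). Pard3 fell from 35.2 ± 1.95 to 18.7 ± 4.76 CPM (−0.89 ± 0.22, adjusted p = 0.00796) and Yap1 rose from 23.7 ± 1.78 to 41.8 ± 1.39 (0.82 ± 0.21, adjusted p = 0.00975). Of 22 P450 genes 17 fell (18 over the list alone; Cyp2f2 −4.43 ± 0.27; adjusted p = 1.73e-16, and adjusted p = 0.0124 with an estimated correlation), of 19 bile acid genes 16 with 1 higher (adjusted p = 0.0124), of 20 hepatocyte maturation genes 13 with 1 higher (adjusted p = 0.000581) and of 19 urea cycle genes 12 with 3 higher (adjusted p = 0.0401). Actin and adhesion genes rose in 9 of 29 with 2 lower (adjusted p = 0.0275). Acute phase (11 of 17 higher, 15 over the list alone; adjusted p = 0.052 with an estimated correlation), pericentral (9 of 15 lower, adjusted p = 0.102) and cholesterol genes (8 of 16 higher with 2 lower, adjusted p = 0.0849) were called with the preset correlation alone. In all 890 genes were higher and 1527 lower. Day 2 control replicate 1 holds only 7 cells. At day 7 against day 0 (n = 4 and 2) edgeR called 0 genes in the controls (633 unadjusted, DESeq2 24; 3 without day 0 replicate 2), with Alb at 49420 ± 4144 and 52020 ± 3600 CPM.

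Before hepatectomy, at day 0, the Pard3HMKO and control livers had 0 genes called by edgeR (994 unadjusted, DESeq2 178). Only the Pard3HMKO labels give an AAV injection, so the adult comparisons include any effect of the injection. Pard3 stood at 38.3 ± 5.22 and 35.2 ± 1.95 CPM and Alb at 49820 ± 11480 and 52020 ± 3600. Urea cycle genes shifted downward with none called (median −0.24, adjusted p = 0.00258, and adjusted p = 0.686 with an estimated correlation).

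Differences appeared 2 days after hepatectomy. In Pard3HMKO the regenerating-family genes Reg3g (219 ± 110 against 0.458 ± 0.647 CPM, 8.19 ± 0.69) and Reg3b (8.64 ± 1.55) were higher, with Mmd2 (7.53 ± 1.81), Cyp8b1 (38.3 ± 10.7 against 0.218 ± 0.309 CPM, 6.66 ± 0.79), A2m (5.07 ± 1.26) and Tm4sf20 (4.57 ± 0.73). The interferon genes Tgtp1 (−6.55 ± 0.94) and Oasl1 (−4.59 ± 0.97) were lower, with Cib3 (168 ± 55.7 to 2.73 ± 1.29 CPM, −5.95 ± 0.87), Akr1b7 (−5.30 ± 1.27) and Id1, which inhibits differentiation factors (−4.56 ± 0.65). Wfdc3 had no read against 14.8 ± 6.26 CPM in controls. Alb was not called (−0.28 ± 0.14). Cholesterol synthesis rose in 10 of 16 genes (15 over the list alone; Insig1 2.18 ± 0.30, Stard4 1.45 ± 0.19; adjusted p = 2.57e-16, and adjusted p = 0.00742 with an estimated correlation) and hepatocyte maturation in 6 of 20 (9 with 1 lower; Hpd 2.91 ± 0.20; adjusted p = 0.00742). Lost with an estimated correlation were complement (8 of 21 higher, 15; adjusted p = 0.299), interferon (3 of 20 lower, 8; adjusted p = 0.091), urea cycle (5 of 19 higher, 8; adjusted p = 0.0711), YAP target genes (0 of 23 called, median −0.78; adjusted p = 0.313), apical junction genes (2 of 35 lower, Cdh1 −1.64 ± 0.37; adjusted p = 0.299) and erythroid markers (0 of 7 called, 6 lower over the list alone; adjusted p = 0.299). The erythroid shift rests on control replicate 1 (4973 CPM, against 11.7 in replicate 2 and 12.4 and 16.2 in Pard3HMKO), and was lost without libraries of under 20 cells. In all 303 genes were higher and 187 lower (2010 unadjusted). The count was 240 or 209 without Pard3HMKO replicate 1 or 2, 256 without control replicate 1 (7 cells) and 1353 without control replicate 2.

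The change from day 0 to day 2 differed between Pard3HMKO and controls in 363 genes (282 higher and 81 lower; 1908 unadjusted). Tm4sf20 (8.73 ± 2.2), Cyp8b1 (6.81 ± 0.95) and Pirb (4.58 ± 1.00) were higher in that difference, and the detoxification genes Gstm3 (−4.48 ± 1.00), Gsta4 (−3.74 ± 0.71) and Aox3 (−3.72 ± 0.24) lower. Cholesterol synthesis (3 of 16 higher, 11 over the list alone; adjusted p = 0.0307 with an estimated correlation), urea cycle (5 of 19, 7; adjusted p = 0.032) and hepatocyte maturation genes (7 of 20, adjusted p = 0.0086) were higher. Without Pard3HMKO day 0 replicate 1 or 2 the count was 131 or 176, without Pard3HMKO day 2 replicate 1 or 2 it was 193 or 115, without control day 0 replicate 1 or 2 it was 147 each, and without control day 2 replicate 2 it was 782.

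By day 7 (n = 6 Pard3HMKO and 4 control libraries) Alb was higher in Pard3HMKO (67880 ± 4236 against 49420 ± 4144 CPM, 0.46 ± 0.09, adjusted p = 0.00366). The urinary protein genes Mup19 (273 ± 66.6 to 17.7 ± 2.64 CPM, −3.95 ± 0.18, adjusted p = 1.85e-11) and Mup9 (−4.40 ± 0.47) and the signalling regulator gene Rgs16 (−4.29 ± 0.60) fell. Cxcl14 (11.9 ± 5.26 against 0.234 ± 0.131 CPM, 5.61 ± 0.49), the collagen gene Col3a1 (5.54 ± 0.67) and Dnaic1 (5.83 ± 1.47) were higher. Dnaic1 held 30.4 and 26.6 CPM in Pard3HMKO replicates 3 and 4, of 12 and 9 cells that all hold markers of other types, and 0.869 to 5.70 CPM in the other 4. Cholesterol synthesis rose in 12 of 16 genes (15 over the list alone; Hmgcs1 1.37 ± 0.14; adjusted p = 3.6e-23, and adjusted p = 0.0029 with an estimated correlation) and actin and adhesion genes in 5 of 29 (9; Tagln2 3.13 ± 0.48; adjusted p = 0.0126). Lost with an estimated correlation were, among others such as S phase, urea cycle, periportal, pericentral, biliary and P450 genes, acute phase (6 of 17 higher, 10; adjusted p = 0.123), interferon (7 of 20 higher, 11; adjusted p = 0.0662), G2 and M phase (6 of 22 higher, 17; adjusted p = 0.247), fatty acid oxidation (6 of 16 lower, 9; adjusted p = 0.0622) and bile acid genes (7 of 19 lower with 1 higher, 10 and 1; adjusted p = 0.193). Markers of other cells moved with them: stellate genes were higher in 5 of 14 (10; Col1a1 3.91 ± 0.73; adjusted p = 0.0622 with an estimated correlation), macrophage genes in 8 of 17 (11; C1qb 2.14 ± 0.41; adjusted p = 0.165) and endothelial genes in 1 of 15 (3; adjusted p = 0.167). Cells with such markers were 28.6% to 100% of the Pard3HMKO libraries and 13% to 21.1% of the controls. edgeR called 425 genes higher and 425 lower (3007 unadjusted). The count was 446 to 966 with 1 library left out and 1584 without libraries of under 20 cells. In 100 divisions of these 10 libraries into 6 and 4, only the real one reached 850 (highest other 400).

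By peak presence, 60 gained and 66 lost regions lay near list genes in Foxa3Cre Pard3HMKO at E17.5 (n = 3 per group). Alphabetically first were those gained at Ankrd1 (19:36119752–36120363), Atf3 (1:191165806–191171346) and Ccn1 (3:145644943–145646994) and lost at Cyp2e1 (7:140763421–140763970), each overlapping its gene. Of 72982 regions 3135 were gained and 2744 lost, with 40509.7 ± 1604.3 and 41175.7 ± 3196.7 peaks per library (exact permutation p = 0.9, smallest possible 0.1). Genes within 10 kb rose more often near gained regions than near lost ones: gained ones lay near 128 higher and 115 lower genes and lost ones near 121 higher and 205 lower (Fisher's exact test, odds ratio 1.89, adjusted p = 0.000359). In the ATAC libraries labelled YapHMKO at E17.5 (n = 3 per group), a label that Yap1 reads contradict in the RNA of the same stage, regions were gained at Ankrd1 (19:36119660–36120410) and Anxa3 (5:96793294–96793690) and lost at Akr1d1 (6:37529899–37530283) and Cyp2e1 (7:140763387–140763957). Here 2348 of 63682 regions were gained and 2172 lost (36319 ± 1064.5 and 38745 ± 3834.1 peaks, exact permutation p = 0.4; odds ratio 1.96, Fisher's exact test adjusted p = 0.00188).

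In culture (n = 2 per group) PD opened regions at Abcb11 (2:69342371–69343159) and Abcg5 (17:84682658–84683231) and closed one at Ankrd1 (19:36119782–36120353). TPPB closed regions at Abcg8 (17:84675966–84676329), Agxt (1:93134950–93135577) and Anxa1 (19:20390417–20390949), and the Pard3HMKO cultures lost the same Agxt and Anxa1 regions against the same controls, and one at Cyp2d10 (15:82407048–82407386). PD given to Pard3HMKO cultures opened regions at Abcb11 (2:69342435–69343300), Abcg5 (17:84682662–84683314) and Agxt (1:93135065–93135571). Gained and lost regions numbered 1988 and 10641 of 55691 for PD, 2005 and 7683 of 57143 for TPPB, 1472 and 6415 of 56450 for Pard3HMKO and 2830 and 4375 of 46805 for PD in Pard3HMKO. The excess of losses follows the number of peaks, 40888.5 ± 7084.5 in the controls, 25897.5 ± 2301.6 with PD, 30379.5 ± 5425.6 with TPPB, 30797 ± 6369.6 in Pard3HMKO and 28103.5 ± 5336.5 with PD in Pard3HMKO (exact permutation p = 0.333, 0.333, 0.333 and 0.667, smallest possible 0.333). With an equal number of peaks per library the counts were 3770 and 4127, 3031 and 3494, 2436 and 2822, and 3238 and 3476.

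Genes near gained regions rose more often than genes near lost regions in culture. With PD, gained regions lay near 383 higher and 130 lower genes and lost regions near 480 higher and 735 lower (odds ratio 4.51, Fisher's exact test adjusted p = 5.45e-41). The odds ratios were 2.68 for TPPB (adjusted p = 6.26e-10), 2.57 for Pard3HMKO (26 higher and 37 lower near gained regions, 41 and 150 near lost ones; adjusted p = 0.0029) and 4.02 for PD in Pard3HMKO (404 and 63, and 214 and 134, so more genes near lost regions rose than fell; adjusted p = 5.66e-16), all by Fisher's exact test.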

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

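Chosen after seeing the results were the tests of double-line cells, retained Yap1 exons and libraries without deleted cells. So were the fits with cells of 1 kind and the ATAC splits. By which genes held reads, 127 of 138 cells (92%) of the 4 double-line libraries at E17.5 matched 1 or 2 single-line cells. The same test matched 2 of 507 cells (0.39%) of the 6 other E17.5 libraries. In 76.8% of the 138 cells no gene with at least 20 reads is missing from the 2 best cells, so stray reads added to cells of their own are unlikely as the source. On simulated merged cells the test found 56 of 60, with 2 of 3659 other cells matched. A possible explanation is that the double-line libraries were assembled from the reads of single-line cells; no biological explanation was tested.

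The libraries labelled YapHMKO at E17.5 hold Yap1 reads in 63 of 63 cells, and YapWT in 94 of 107. The share is 1.138 times that of the controls, so a mixture with control cells is unlikely. Exons left in place by the deletion are an unlikely source too, since the same label at E15.5 gave −5.02. The change of 0.67 at E17.5 fits libraries without Yap1-deleted cells, a mislabelled sample being a candidate explanation. Outgrowth by E17.5 of the cells with Yap1 reads at E15.5 (14 of 49) is a biological alternative that was not tested.

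The share of cells with Xist or Y transcripts differs between Pard3HMKO and controls at E17.5 (20 of 65 cells with Xist against 0 of 115), E19.5, P0 and P14, and sex could account for part of the calls. With cells of only 1 kind in both groups, 89.1% of the called genes were kept at E17.5 (91.3% for the labelled Yap line), 82.1% at E19.5 and 86.8% at P0. Sex is thus an unlikely source of most of them there. At P14 both groups share 0 cells of 1 kind, so the effects of sex and of the deletion cannot be told apart. The effect of sex within the deletion was not tested.

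Odds ratios of 1.89, 1.96, 4.51, 2.68, 2.57 and 4.02 compare the share of risen genes near gained regions with that near lost regions, for Pard3HMKO and the libraries labelled YapHMKO at E17.5 and, in culture, for PD, TPPB, Pard3HMKO and PD in Pard3HMKO. Only 1 of 100 divisions of the adult day 7 libraries gave as many genes as the real 850, the highest other being 400; for PD and TPPB fitted with their own 8 libraries it was 1 of 35 each (3361 against 43, and 1843 against 83). For ATAC at E17.5 the 10 divisions are too few: the real ones gave 5879 and 4520 regions and the highest others 467 and 516.

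Far from the other libraries of their group at day 7 stood the stellate marker sum of Pard3HMKO replicate 3 (247.4 CPM, others 31.47 to 90.99), Pard3 in control replicate 3 (39.59 CPM, others 44.12 to 44.69) and Dnaic1 in control replicate 1 (0.7309 CPM, others 0 to 0.04324). They are 3 of 34 measures tested, and chance alone sets apart about 1 in 20. A test of the difference between groups called 540 genes between the Foxa3Cre and AlfpCre changes at E17.5, 2721 between P14 and E17.5, 2899 between P14 and P0, 1549 between the labelled Yap changes at E17.5 and E15.5, 5 between the labelled Yap and Pard3 changes at E17.5, 1 between the labelled double and Pard3 changes, 135 between the answers to PD, and 363 between the adult responses at day 2. Outside the main measurement, spike-in sequences held 0.042 CPM over all libraries.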

How the results depend on the processing

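The fits without the double-line libraries, with cells of 1 kind (E17.5, E19.5 and P0), without the E15.5 and E16.5 wild-type libraries and without libraries of under 20 cells were chosen after seeing the data. Of the named values only Yap1 for PD in YapHMKO cultures, not called with all libraries, turned its direction: it was −0.73 without control replicate 1 and 1.81 without control replicate 2. Named calls were lost in 1652 of 12044 values with a library left out, 381 of 2150 without cells holding markers of other types, 284 of 2023 with only the libraries compared and 149 of 2160 with the replicate block. Counts stayed within 1.5 times with RLE normalization (32 of 32), without the double-line libraries (11 of 11), with cells of 1 kind, and in 106 of 170 fits with a library left out. Of 435 list tests called, 207 were called with an estimated correlation.

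With no filter on low counts, more genes were tested and the counts were 104 at E11.5, 72 at E13.5, 286 at E15.5, 466 for Yap at E15.5, 28 for the double against the Pard3 change, 395 and 713 for the control lines at E17.5 and in culture, 103 for PD against U0126, 1349 for Pard3HMKO in culture, 686 for the answers to PD, 35, 811 and 1538 for adult days 0, 2 and 7, 75 for control day 7 against day 0 and 609 for the day 2 responses.

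Fitted with only the libraries compared, which leaves fewer libraries to estimate the spread, they were 0 at E11.5, 0 at E15.5, 578 with AlfpCre, 6 for Yap at E15.5, 2 for the double against the Pard3 change, 41 and 57 for the control lines, 2 for PD against U0126, 368 for Pard3HMKO and 292 for YapHMKO in culture, 1635 for PD in YapHMKO, 203 for adult day 2, 1333 for control day 2 against day 0 and 6 for day 7 against day 0.

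As a replicate block the numbers gave 8 at E11.5, 28 at E15.5, 28 for Yap at E15.5, 468 at adult day 7 and 161 for the day 2 responses; libraries share only a number, with correlations from −0.05 to 0.06, and the replicate block moved no other count beyond 1.5 times.

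Without cells holding markers of other types they were 2 at E11.5, 6 at E13.5, 17 at E15.5, 1082 at E17.5, 381 at E19.5, 145 with AlfpCre, 10 for Yap at E15.5, 1071 and 1083 for the labelled Yap and double lines at E17.5, 18 and 514 for the control lines, 48 and 523 for adult days 0 and 7 and 2 for control day 7 against day 0; the cause was not tested. DESeq2 called 30 at E11.5, 3 at E13.5, 141 at E15.5, 302 for Yap at E15.5, 7 for the double against the Pard3 change, 263 and 520 for the control lines, 3 for PD against U0126, 1364 for Pard3HMKO in culture, 467 for the answers to PD, 178, 801 and 1489 for adult days 0, 2 and 7, 24 for control day 7 against day 0 and 665 for the day 2 responses. Simulated DESeq2 calls, none for in vivo lines, were 12% to 23.1% false, against 1.4% to 3.8% with edgeR. The wild-type trend from E13.5 to E17.5 called 3411. Without libraries of under 20 cells adult day 7 gave 1584 and the day 2 responses 891; the cause was not tested. With an equal number of peaks the ATAC comparison of PD gave 7897.

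With 1 library left out the counts ranged 0 to 1 at E13.5, 19 to 63 at E15.5, 1605 to 2182 at E17.5, 586 to 794 at E19.5, 485 to 909 with AlfpCre, 36 to 64 for Yap at E15.5, 1562 to 1778 and 1512 to 1945 for the labelled Yap and double lines at E17.5, 27 to 73 and 84 to 205 for the control lines, 1115 to 1501 for U0126, 0 to 2 for PD against U0126, 330 to 574 for Pard3HMKO in culture, 1245 to 1728 and 1664 to 2174 for PD and U0126 in it, 32 to 78 for the answers to PD, 726 to 1363 for YapHMKO in culture, 2048 to 3035 for PD in it, 209 to 1353 and 446 to 966 for adult days 2 and 7, 1462 to 2992 and 0 to 3 for control days 2 and 7 against day 0, and 115 to 782 for the day 2 responses. For ATAC they ranged 5807 to 6952 for the labelled Yap line, 16275 to 24675 for PD, 14639 to 20528 for TPPB, 13084 to 18190 for Pard3HMKO and 11250 to 14789 for PD in it; a rule over fewer libraries calls more regions.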

Other observations

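This comparison was chosen after seeing the data, was not tested, and scales each side in its own fit. The E11.5 Foxa3Cre controls held 891 CPM of Alb and 9160 of Afp, and B6C3F1 livers of that age 19430 ± 68.4 and 39420 ± 226 CPM.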
